A study of Mus musculus with 18 samples.

How the data were processed

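The series holds 18 Affymetrix whole-transcript mouse arrays in 6 groups of 3: soleus and quadriceps of mice with and without inducible loss of EglN1 in skeletal muscle, and hearts of mice given FG-4497 or vehicle. The deposited values were on a log2 scale, made by the authors with robust multi-array average (RMA), per the submitters' processing notes. RMA corrects background, normalizes by quantiles between arrays and combines the probes of a transcript. The version and the set of arrays normalized together are not given in the sources used here. No further normalization was applied for the main results. Raw image files were not used here.

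Of 35556 probe sets, 21789 named 1 gene in the platform annotation, 1621 named several and 12146 were not listed with a gene. Symbols were brought up to date through gene identifiers for 21698 probe sets with a table of the GRCm38.p6 assembly. Each of 19938 genes was represented by its brightest probe set. Genes with a mean below the 40th percentile were left out, which is 6.19 for muscle and 6.26 for heart, and left 13319 and 13432 genes. Where all arrays of 1 group lay below this level, the change of a named gene is given as at least the distance of the other group's mean from it, a choice made after the values were seen. No column was left out and no pair of columns was identical. Intensity arrays have no read depth, so the number of arrays, 3 per group, limits precision.

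Tests were run in R 4.3.3 with limma 3.58.1. The 12 muscle arrays were fitted together with 4 group means and animal as a random block (consensus correlation 0.17), and the contrasts were KO minus WT in soleus, KO minus WT in quadriceps, the difference of these, and soleus minus quadriceps in WT. The 6 heart arrays had their own fit. Genes were called at a Benjamini-Hochberg adjusted p under 0.05, and log2 changes are given with standard errors from the moderated fit. With 3 against 3 arrays the smallest exact p of a rank or permutation test is 0.1, so per-gene tests rest on the pooled variance of limma. The block comes from numbers in the labels that join 1 soleus and 1 quadriceps array of the same genotype, read here as animal numbers, which the labels do not state. As a check, the deviations of these 6 pairs from their group means correlated at r from -0.0008 to 0.378, with 4 above 0.1.

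The comparisons, the gene lists, the rule for named genes and the alternatives of the main plan were fixed before the data were examined. The rule takes, per comparison, the 10 called genes with the largest rise and the 10 with the largest fall among those whose groups do not overlap, without predicted genes, together with the oxygen sensing and kynurenine genes Egln1, Egln2, Egln3, Hif1a, Epas1, Vegfa, Kyat1, Kyat3 and Got2 and, from each list, up to 4 called members with the largest change or else the member with the largest change. A comparison with fewer than 5 called genes also names the 5 with the smallest p, as not passing. Genes named outside this rule were chosen after their values were seen: members that passed only when adjusted over a list alone, fibre myosins beyond the rule, further members of called lists in heart, and genes shared between comparisons. A gene that the rule names in quadriceps is not reported here.

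The 26 lists held 350 genes, 323 of them measured: HIF targets, oxygen sensing, glycolysis, glycogen, TCA cycle, oxidative phosphorylation, fatty acid oxidation, tryptophan and kynurenine, amino acid transamination, iron handling, slow fibre, fast fibre, muscle regeneration, cardiac stress, cardiomyocyte, endothelial, smooth muscle and pericyte, fibroblast and matrix, macrophage and leukocyte, erythroid, adipocyte, nerve and Schwann cell, immediate early and heat shock, circadian clock, interferon response and sex-linked genes. Lists with at least 5 tested genes, 23 in each comparison, were tested with limma's cameraPR on the moderated statistics with a preset inter-gene correlation of 0.01, adjusted over the lists of a comparison, and again with the correlation estimated from residuals. Of these, 1, 4, 5, 9 and 6 lists were called in soleus, quadriceps, their difference, WT muscles and heart, and 0, 1, 3, 3 and 5 with the estimated correlation. Correlation estimates below 0 were set to 0, which made the second test less strict than the first. Among called lists, this applied in heart to HIF targets, immediate early and heat shock genes and endothelial markers. Members were also counted after an adjustment over the list alone. Median, mean and test of a list differed in sign for 2 lists in soleus (oxygen sensing, tryptophan and kynurenine), 4 in quadriceps (HIF targets, tryptophan and kynurenine, iron handling, interferon response), 6 in the difference (HIF targets, oxygen sensing, glycogen, tryptophan and kynurenine, smooth muscle and pericyte, adipocyte), 2 in WT muscles (oxygen sensing, cardiomyocyte) and 7 in heart (oxygen sensing, TCA cycle, tryptophan and kynurenine, iron handling, fast fibre, muscle regeneration, adipocyte), none of them called.

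The procedure was tested on simulated data, drawn with normal noise around each gene's measured mean with its moderated variance, with known changes added to 200 genes. Changes of 0.5, 1 and 2 on the log2 scale were recovered for 85.1%, 98.5% and 100% of genes in soleus, 92.5%, 97% and 100% in quadriceps and 82.1%, 100% and 100% in heart, with 5 false calls of 195, 14 of 207 and 12 of 200. A glycolysis list shifted by 0.15 was called (cameraPR, adjusted p = 0.0122) and 0 of the 22 other lists were. The noise was drawn independently for each gene. The simulation therefore cannot show how often lists of genes that move together are falsely called with the preset correlation.

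Alternatives covered normalization, the choice of probe set, the filter, the variance prior, array weights, blocking, the arrays in the fit, the inter-gene correlation and each replicate left out. A pair of further ones was chosen after the data were seen: the mean of the slow fibre list per array as a covariate, and a fit without the array farthest from its group in fibre markers in each muscle (soleus WT replicate 2 and quadriceps KO replicate 2). Overlaps between comparisons were tested with Fisher's exact test. Results were also computed for each of the 10 ways to split 6 animals or arrays 3 against 3. Gene order along the genome was taken from the same assembly table, since the files name no build.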

Results

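Gene expression was measured on 18 whole-transcript mouse arrays, 3 in each of 6 groups. Soleus, a slow postural muscle of the calf, and quadriceps, a mostly fast muscle of the thigh, came from 6 mice if numbers in the labels are read as animal numbers, as was done here. In 3 of these mice (KO), a floxed Egln1 gene was removed by a Cre recombinase of skeletal muscle that tamoxifen, given for 3 days, switches on. The other 3 (WT) carried the same recombinase without the floxed gene and were given tamoxifen too. Egln1 encodes EglN1 (also called PHD2), the prolyl hydroxylase that marks the alpha subunits of the hypoxia-inducible factors (HIF) for degradation when oxygen is present. In a separate experiment, hearts were taken from mice given FG-4497, a small-molecule inhibitor of the EglN enzymes, at 50 mg per kg into the peritoneum, or given vehicle. Arrays were alike in overall signal, with medians between 6.68 and 6.81 on the log2 scale, and replicates of a group correlated at r between 0.986 and 0.995 across probe sets. With 3 arrays per group, the number of arrays limits the precision of every value.

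Egln1 itself was read first in every array. In soleus, the KO arrays read 11.03, 11.07 and 11.12 on the log2 scale and the WT arrays 11.29, 11.22 and 11.31, a difference of -0.20 with a standard error (SE) of 0.07 (limma, adjusted p = 0.438). In quadriceps, the KO arrays read 10.87, 10.67 and 10.92 and the WT arrays 10.94, 10.99 and 10.95, a difference of -0.14 (SE 0.07, adjusted p = 0.471). Every KO array lay below every WT array of the same muscle, and neither difference passed the test over all genes. Chance alone gives such a separation, in either direction, for 10% of genes. The labels do not say which part of the gene was deleted, and 1 probe set summarises the whole transcript. These values are therefore only a limited check of the genotype. In heart, vehicle arrays read 11.37, 11.34 and 11.50 and FG-4497 arrays 11.63, 11.66 and 11.65, a difference of 0.24 (SE 0.08, adjusted p = 0.225; 0.0274 with a trended, robust prior).

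**Figure D1:**
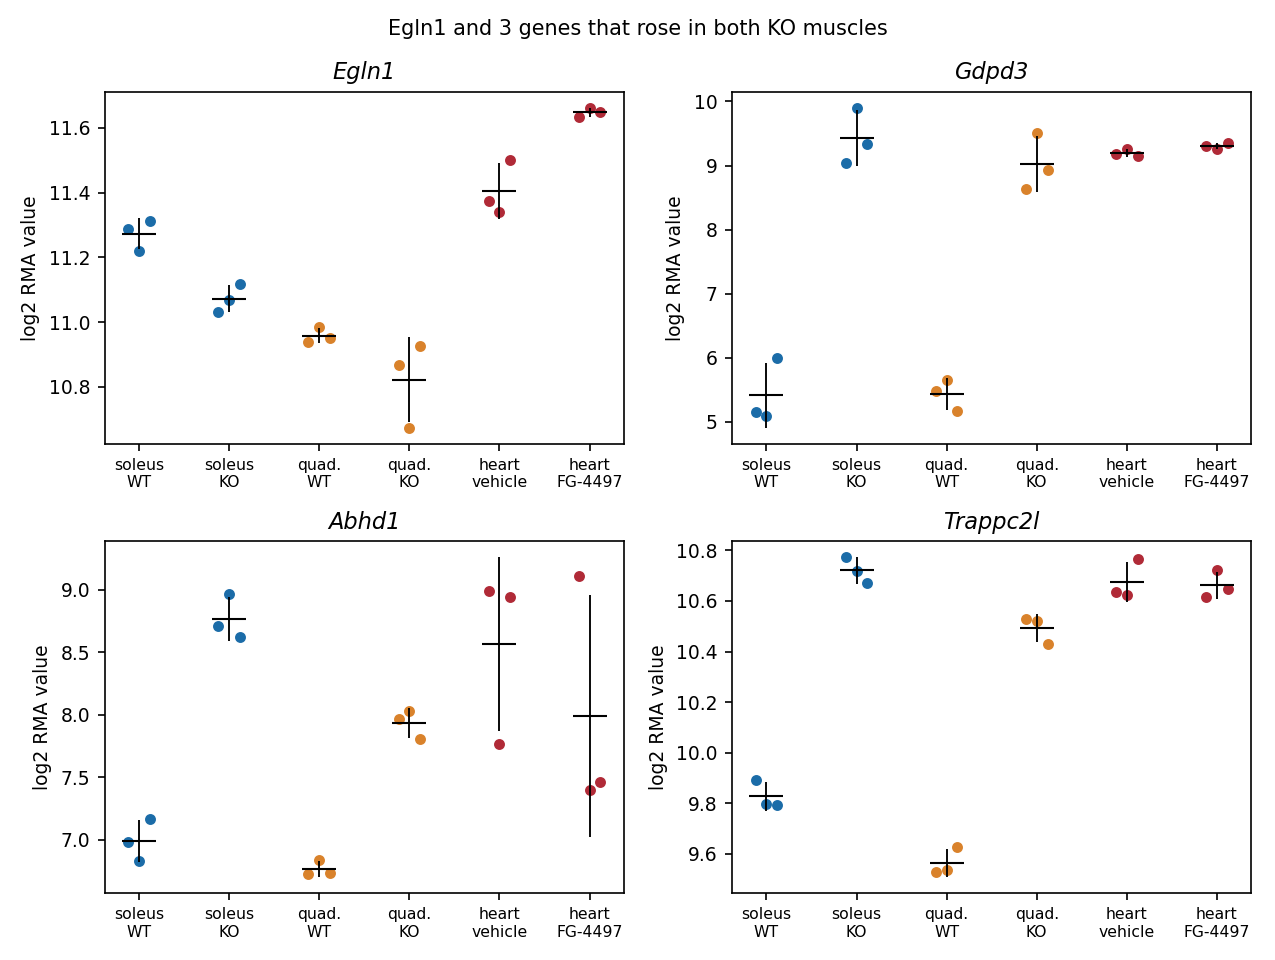
Log2 values of Egln1, Gdpd3, Abhd1 and Trappc2l on each of the 18 arrays (points), with the mean and SD of each group of 3 (bars); each panel has its own axis range. Gdpd3 lay at 5.41 and 5.43 in WT soleus and quadriceps against 9.43 and 9.02 in the KO muscles, while the group means of Egln1 differed by -0.20 in soleus and -0.14 in quadriceps.

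The first comparison asked which genes differed between KO and WT mice in soleus. Of 13319 genes tested, 24 changed, 16 higher and 8 lower in KO than in WT. Gdpd3, a phosphodiesterase of lysophospholipids, showed the largest rise, from 5.41 ± 0.51 to 9.43 ± 0.43 (SD, n = 3; limma adjusted p = 5.94e-06). Its WT values lay below the filter level of 6.19 in both muscles, so its rise is given as at least 3.23 on the log2 scale. Serpina3n, a secreted serine protease inhibitor of the acute-phase response, rose 4.04-fold (SE 0.29 on the log2 scale, adjusted p = 0.0115; call lost in 6 of 18 alternatives). Abhd1, a protein of the alpha/beta-hydrolase fold, rose 3.42-fold (SE 0.10, adjusted p = 2.37e-06), and Trappc2l, a subunit of the TRAPP complexes that tether transport vesicles, 1.86-fold (SE 0.06, adjusted p = 5.94e-06). Smaller rises were those of Lrch1, a leucine-rich repeat protein (log2 0.81), Tmem37, a relative of calcium channel gamma subunits (0.64), and Ppwd1, a prolyl isomerase found with the spliceosome (0.64). Probe sets of 3 microRNA genes were also higher, Mir181b-2 by 0.98, Mir16-1 by 0.73 and Mir30c-2 by 0.65 on the log2 scale. Calls were lost in 5 of 18 alternatives for Mir181b-2, 4 of 18 for Ppwd1, 3 of 18 for Tmem37, 2 of 18 for Lrch1, 2 of 16 for Mir16-1 and 1 of 17 for Mir30c-2.

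The 8 genes lower in KO soleus were led by Ostn, which encodes the secreted muscle peptide musclin (log2 change -0.92, SE 0.13, adjusted p = 0.0121). Piwil2, an Argonaute-family protein of the piRNA pathway, fell to values below the filter level, by at least 0.49, and Socs2, a feedback inhibitor of growth hormone signalling, by 0.65 on the log2 scale. Kif5b, the heavy chain of kinesin-1, fell by 0.63 from 11.16 ± 0.09 to 10.53 ± 0.08 (SD, n = 3, adjusted p = 0.00104). Log2 changes of the remaining 4 were -0.49 for Efr3b, a membrane anchor of phosphatidylinositol 4-kinase (call lost in 10 of 18 alternatives), -0.47 for Def8, a regulator of lysosome position, -0.41 for Serinc2, a multipass membrane protein, and -0.38 for Wwox, an oxidoreductase with WW domains. The calls of Socs2, Serinc2, Wwox and Ostn were lost in 9, 8, 7 and 4 of 18 alternatives, those of Def8 and Kif5b in 1 of 18 and that of Piwil2 in 1 of 16. Of the enzymes and factors of the oxygen-sensing pathway other than Egln1, the log2 differences were -0.13 for Egln2, -0.12 for Egln3, 0.06 for Hif1a and 0.01 for Epas1, and none passed (adjusted p from 0.681 to 0.991).

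The list of HIF target genes did not stand apart in KO soleus. Of 30 measured members none was called, over all genes or when adjusted over the list alone, and the list's median log2 difference was 0.025 (limma's cameraPR test, adjusted p = 0.651; 965 genes passed an unadjusted p of 0.05 in this comparison). Its widest difference was that of Adm, adrenomedullin, at 0.39 (SE 0.15, adjusted p = 0.56), and Vegfa, the vascular growth factor, stood at -0.01 (SE 0.08). Only the circadian clock list was called in soleus, with a median of 0.22 (adjusted p = 0.00529). That call was lost at adjusted p = 0.469 with an estimated correlation. None of its 14 measured genes passed over all genes tested, and 6 were higher and 2 lower when adjusted over the list alone. Among these were Arntl, the clock activator BMAL1, at -0.80 (passing over all genes in 1 of 18 alternatives) and Dbp, a clock output factor named after its value was seen, at 0.40. The clock call was also lost without soleus WT replicate 1 (adjusted p = 0.227) and without soleus WT replicate 3 (adjusted p = 0.0508). Immediate early and heat shock genes had a median of -0.09 (adjusted p = 0.07), with 4 of 12 lower when adjusted over the list alone, Fos among them at -0.86 (passing over all genes in 1 of 17 alternatives). The tryptophan and kynurenine list, which holds the aminotransferases of kynurenine, had a median of -0.0026 while its mean and its test pointed up (adjusted p = 0.674), with Kyat1 at -0.03, Kyat3 at 0.04 and Got2 at 0.01. The other 19 tested lists were not called either (adjusted p from 0.146 for endothelial markers to 0.809 for glycogen enzymes).

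All 24 genes called in soleus had groups of arrays that did not overlap, as had 12.3% of all tested genes, where chance gives 10%. Fast-fibre content varied between the soleus samples: Myh4, the fast IIB myosin, ranged from 8.99 to 13.31 among the WT arrays and from 12.48 to 12.73 among the KO arrays. The count of 24 became 62 with estimated array weights, 12 from the 6 soleus arrays alone and 15 without the array farthest from its group in fibre markers in each muscle. Quantile normalization repeated over the muscle arrays gave 11 higher and 9 lower. It was 7, 13 and 43 without soleus KO replicates 1, 2 and 3 and 12 without soleus WT replicate 1.

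In quadriceps, the same comparison called 91 of 13319 genes, 37 higher and 54 lower in KO. Gdpd3 again rose most, from 5.43 ± 0.25 to 9.02 ± 0.44 (SD, n = 3; at least 2.83 on the log2 scale, limma adjusted p = 3.36e-05), and Serpina3n rose 3.86-fold (SE 0.29 on the log2 scale, adjusted p = 0.00878). Lrmda, a leucine-rich repeat protein of melanocyte differentiation, rose 2.26-fold (adjusted p = 0.0415; call lost in 12 of 17 alternatives, adjusted p up to 0.160). Abhd1 rose 2.25-fold (adjusted p = 0.000117) and Trappc2l 1.91-fold (adjusted p = 8.37e-06). Stc2, a secreted glycoprotein and the only called member of the HIF target list, rose by 0.78 on the log2 scale (SE 0.13, adjusted p = 0.0219; call lost in 5 of 18 alternatives). Log2 rises of the other leading genes were 1.00 for Mir181b-2 and 0.92 for Mir181a-2, 0.81 for Ppwd1 and 0.72 for Mid1ip1, which promotes polymerisation of acetyl-CoA carboxylase. The calls of Serpina3n, Mir181b-2 and Ppwd1 were each lost in 1 of 18 alternatives.

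Unc5a, a netrin receptor, showed the largest fall in quadriceps, from 9.09 ± 0.02 to 7.53 ± 0.61 (SD, n = 3; log2 -1.56, SE 0.22, adjusted p = 0.00564; call lost in 2 of 18 alternatives). Tmem267 fell by 1.18 and Polk, a DNA polymerase of lesion bypass, by 0.99 on the log2 scale (adjusted p = 0.00485 and 0.000755). Arntl fell by 0.95 (SE 0.18, adjusted p = 0.0408; call lost in 10 of 18 alternatives), and Cpeb1, a regulator of cytoplasmic polyadenylation, by 0.84 (adjusted p = 0.0105; call lost in 5 of 18 alternatives). Other leading falls, in log2 units, were -0.83 for Socs2, -0.70 for Ppp1r27, a regulatory subunit of protein phosphatase 1 (call lost in 7 of 18 alternatives), -0.69 for Cacng7, a calcium channel gamma subunit, and -0.66 for Tmem140. The calls of Socs2 and Tmem140 were each lost in 1 of 18 alternatives. Egln2, Egln3, Hif1a, Epas1 and Vegfa did not pass, with log2 differences of -0.14, 0.36, 0.16, 0.06 and 0.02 (adjusted p from 0.282 to 0.968).

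Genes of fatty acid oxidation rose as a group in KO quadriceps. Their median log2 change was 0.17 over 16 measured members (cameraPR, adjusted p = 1.17e-12; adjusted p = 0.00698 with an estimated correlation). That test compares genes with genes. An exact permutation test of the list means per array gave p = 0.1, the smallest possible with 3 against 3 arrays. Over all genes only Cd36, the fatty acid transporter, was called, at 0.30 (SE 0.06, adjusted p = 0.0408). Its call was lost in 11 of 18 alternatives, with an adjusted p up to 0.293. When adjusted over the list alone, 10 of 16 were higher. Among these, named after their values were seen, were Acadl, the long-chain acyl-CoA dehydrogenase, at 0.29, Etfa, an electron transfer flavoprotein subunit, at 0.25, and Hadhb of the trifunctional protein at 0.22. The tricarboxylic acid (TCA) cycle list had a median of 0.071 (adjusted p = 0.00713). This call was lost at adjusted p = 0.424 with an estimated correlation and at adjusted p = 0.0661 without quadriceps KO replicate 1. The 1 called member of the 18 in this list was Idh1, the cytosolic isocitrate dehydrogenase, at 0.46 (adjusted p = 0.0415, call lost in 11 of 18 alternatives), also the 1 higher when adjusted over the list alone. Being cytosolic, Idh1 acts outside the mitochondrial cycle, and it had another called gene within 10 tested genes along the genome. Oxidative phosphorylation genes had a median of 0.047 (adjusted p = 0.0367; adjusted p = 0.379 with an estimated correlation) and 0 of 23 called either way. Muscle regeneration genes had a median of 0.091 (adjusted p = 0.0367; adjusted p = 0.174 with an estimated correlation) and 0 of 11 called either way, the widest difference being that of the myogenic factor Myf5 at 0.34. The oxidative phosphorylation call was lost without quadriceps WT replicates 1 and 3 and KO replicates 1 and 2 (adjusted p of 0.064, 0.0843, 0.0663 and 0.172). The regeneration call was lost without WT replicate 2 and KO replicates 1 and 2 (adjusted p of 0.254, 0.0511 and 0.157). With quantile normalization repeated, no filter on low values, or the slow fibre level as a covariate, neither call held (adjusted p from 0.0554 to 0.0942).

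**Figure D2:**
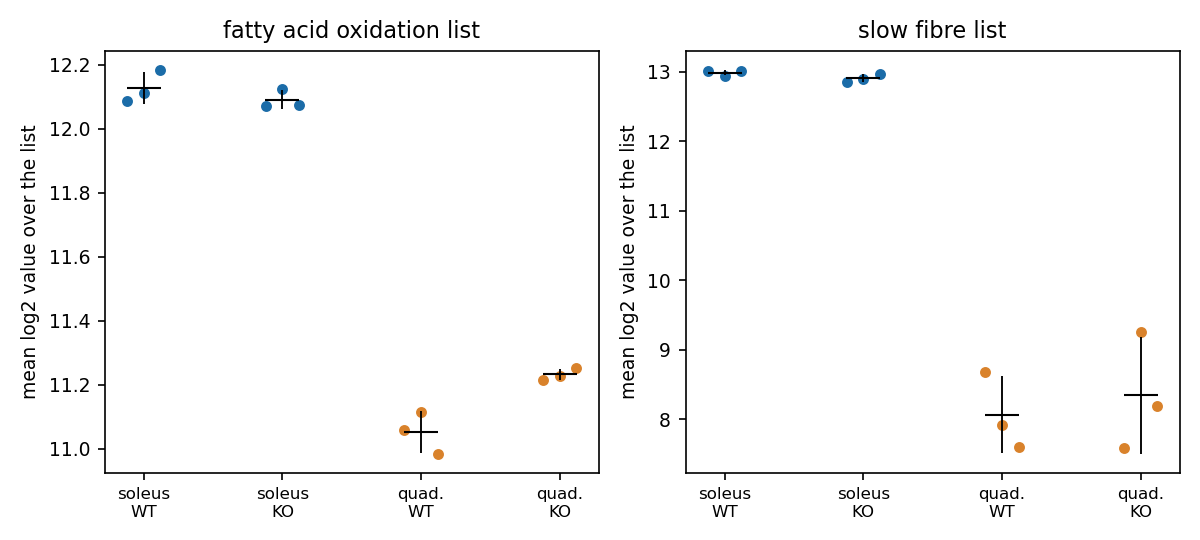
Mean log2 value over the measured genes of the fatty acid oxidation list (left, 16 genes) and the slow fibre list (right, 11 genes) on each muscle array (points), with the mean and SD of each group of 3 (bars). In quadriceps, the 3 KO arrays lay between 11.22 and 11.25 for fatty acid oxidation, above the WT arrays at 10.98 to 11.11, while the slow fibre means of KO and WT overlapped.

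The HIF target list was not called in quadriceps. Its median was 0.0007, its mean -0.015 and its test pointed up, so these differed in sign (adjusted p = 0.619). Of its 30 measured members, 1 was higher (Stc2), and 1 higher and 1 lower when adjusted over the list alone, the latter being Pfkfb3, the glycolytic regulator, at -1.14. The circadian clock list missed the threshold (median 0.11, adjusted p = 0.0917), with Arntl called over all genes and 4 higher and 3 lower of 14 when adjusted over the list alone. Iron handling genes were not called as a list (median 0.025, mean and test pointing down, adjusted p = 0.951). Of 11, 2 were lower when adjusted over the list alone, among them Slc11a2, the divalent metal transporter, at -0.39 (adjusted p = 0.0462; call lost in 11 of 18 alternatives). Immediate early and heat shock genes were not called either (adjusted p = 0.193), with the chaperone Hsph1 at -0.37 (adjusted p = 0.0226; call lost in 8 of 18 alternatives). Slow fibre genes had a median of 0.18 and were not called (adjusted p = 0.128). Their levels moved apart between arrays: Myh7, the slow myosin, ranged from 6.60 to 9.39 in KO and from 6.78 to 8.60 in WT quadriceps, and Myoz2, a Z-disc protein of slow fibres, differed by 0.99 (adjusted p = 0.163, passing in 2 of 18 alternatives). The remaining 14 lists had adjusted p from 0.119 to 0.855 and were not called.

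All 91 genes called in quadriceps had groups that did not overlap, against 16.5% of all tested genes. The count of 91 became 42 with no filter on low values, 197 with estimated array weights, 25 from the 6 quadriceps arrays alone, 48 with the slow fibre level of each array as a covariate and 33 without the array farthest from its group in fibre markers in each muscle. It was 59, 34 and 27 without quadriceps WT replicates 1, 2 and 3, and 29 and 45 without KO replicates 1 and 2.

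The KO effects of both muscles were then set against each other. Of the 24 genes called in soleus and the 91 in quadriceps, 16 were shared, 12 higher and 4 lower in both, where independent lists would share 0.164 (Fisher's exact test, p = 3.95e-30). By the labels' numbers both lists came from the same 6 animals, which this test ignores. Beside Gdpd3, Serpina3n, Abhd1, Trappc2l, Ppwd1, Socs2 and Mid1ip1 they held Tmem37, Piwil2, Serinc2, Def8, Mir181b-2 and Mir30c-2, and, named after their values were seen, Phyhip, Clmn and Abcb10, a mitochondrial transporter of haem synthesis. Of these shared genes, Abhd1, Serpina3n, Clmn, Ppwd1, Piwil2, Phyhip, Def8 and Abcb10 had another called gene within 10 tested genes along the genome. Trappc2l, Def8 and Abcb10 lay near Egln1. Segments of another strain would be present in both muscles of an animal, so sharing alone does not show a response to EglN1 loss. Across genes the log2 changes correlated at r = 0.48, against 0.117 to 0.405 when the 6 animals were divided in the other 9 ways, which each mix KO and WT animals. Genes are not independent replicates. Tests of the difference between the KO effects called 0 genes (limma, adjusted p under 0.05; 851 genes passed an unadjusted p of 0.05). Kif5b came closest, at -0.63 in soleus against 0.02 in quadriceps (difference -0.65, SE 0.08, adjusted p = 0.0525). It passed in 4 of 17 alternatives, with an adjusted p from 0.00719 to 0.469 over all of them. Next, also not passing in the first analysis, were Polk at -0.13 against -0.99 (adjusted p = 0.109, passing in 2 of 17 alternatives), the death ligand Tnfsf10 (0.55 against -0.27, adjusted p = 0.198), 1110002L01Rik (0.37 against -0.36, adjusted p = 0.217) and the Wnt agonist Rspo3 (-0.15 against 0.49, adjusted p = 0.243). Without the animal of soleus WT replicate 2, this test called 2 genes.

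By list, the KO effect was lower in soleus than in quadriceps for fatty acid oxidation, by a median of -0.23 (cameraPR, adjusted p = 3.14e-17; adjusted p = 0.000553 with an estimated correlation). The list tests of this paragraph compare genes with genes and do not measure spread over the animals. Over all genes 0 of 16 members were called, and 9 were lower when adjusted over the list alone. Muscle regeneration genes differed by -0.21 (adjusted p = 0.00106; adjusted p = 0.00989 with an estimated correlation), with 0 of 11 called either way. Chrna1, the acetylcholine receptor subunit, was the widest apart at -0.27 in soleus and 0.29 in quadriceps. Oxidative phosphorylation differed by -0.071 (adjusted p = 0.000307; adjusted p = 0.0453 with an estimated correlation), with 0 of 23 called either way. For the TCA cycle (-0.083, adjusted p = 0.000103) and the slow fibre list (-0.27, adjusted p = 0.0309) the calls were lost with an estimated correlation, at adjusted p = 0.166 and adjusted p = 0.957. No member of either was called. The slow fibre difference turned to 0.037 without the animal of soleus KO replicate 2 (adjusted p = 0.861), and its call was lost without the animals of soleus WT replicates 1 and 3 (adjusted p = 0.338 and 0.16) and with estimated array weights (adjusted p = 0.401). For HIF targets no difference was called (median -0.0026, mean 0.053, adjusted p = 0.943), and the other 17 lists were not called (adjusted p from 0.116 to 0.976).

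Soleus and quadriceps of WT mice were compared to describe the baseline of both muscles. They differed in 6085 genes, 2837 higher and 3248 lower in soleus, and 53% of all tested genes had groups that did not overlap. Slow sarcomere genes led the differences. Tnnc1, slow troponin C, was 91.6-fold higher in soleus (13.43 ± 0.05 against 6.92 ± 0.78, SD, n = 3; limma adjusted p = 1.12e-07). Tnni1, Tnnt1, Myl2, Myl3 and Myh7 were 60.2 to 68.2-fold higher. Tpm3, slow tropomyosin, was 20.6-fold (log2 4.37; 2.33 with the mean of its probe sets) and Atp2a2, the slow calcium pump, 17.1-fold higher. Lgi1 and Tecrl, whose values in quadriceps lay below the filter level, were higher by at least 4.85 and 3.66 on the log2 scale. Lower in soleus were Mstn, the growth inhibitor myostatin (log2 -4.00), Tspan8 (-3.66), Mybph (-3.44), Pfkfb3 (-3.37), Cyp4f39 (-3.10), Atp1b2 (-3.00), Myh4 (-2.95, SE 0.65; -4.08 to -1.89 with 1 animal left out), Actc1, cardiac actin (-2.90), Pla2g7 (-2.87) and Gpd2 (-2.84). Among oxygen sensors, Egln3 was 3.15-fold higher in soleus (adjusted p = 4.14e-06), Egln2 lower by a log2 change of -0.87 (adjusted p = 4.38e-08), and Egln1, Hif1a, Epas1 and Vegfa higher by 0.31, 0.44, 0.57 and 0.30, the call of Vegfa being lost in 2 of 12 alternatives.

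All 11 slow fibre genes were higher in WT soleus (median 5.91, cameraPR, adjusted p = 1.05e-23; adjusted p = 0.0027 with an estimated correlation). So were all 16 genes of fatty acid oxidation (median 1.04, adjusted p = 1.11e-32; adjusted p = 1.17e-07 with an estimated correlation). Of oxidative phosphorylation 22 of 23 were higher (median 0.29, adjusted p = 6.33e-06; adjusted p = 0.00837 with an estimated correlation). These counts were the same when adjusted over the list alone. The TCA cycle (median 0.35, 15 of 18 higher, adjusted p = 1.81e-05), fast fibre (median -0.73, 11 of 12 lower, adjusted p = 6.33e-06), glycogen (-0.69, 4 higher and 6 lower of 11, adjusted p = 0.00293) and glycolysis lists (-0.35, 3 higher and 8 lower of 15, adjusted p = 0.0234) were called with the preset correlation, each lost at adjusted p = 0.107 with an estimated correlation. The glycolysis call was also lost without the animals of soleus WT replicates 1 and 3 (adjusted p = 0.056 and 0.0592) and with animal as a fixed block (adjusted p = 0.0929). Vessel markers were higher too, with 11 of 12 endothelial genes (median 0.58, adjusted p = 0.000182) and 7 of 10 smooth muscle and pericyte genes (median 0.46, adjusted p = 0.000568; 9 when adjusted over the list alone). Both calls were lost at adjusted p = 0.14 with an estimated correlation. The 14 lists not called were those of HIF targets (9 higher and 11 lower of 30, adjusted p = 0.743), oxygen sensing (0.951), tryptophan and kynurenine (0.323), amino acid transamination (0.336), iron handling (0.947), muscle regeneration (0.0829), cardiac stress (0.0829), cardiomyocyte (0.956), fibroblast and matrix (0.745), macrophage and leukocyte (0.722), adipocyte (0.336), immediate early and heat shock (0.722), circadian clock (0.323) and interferon response (0.743). Erythroid, nerve and sex-linked genes had fewer than 5 measured members and were not tested as lists. Alas2, the erythroid haem enzyme, differed by 0.11 (adjusted p = 0.772), Pmp22 and Mbp of myelin were 1.06 and 0.74 higher in soleus, and Eif2s3y was 0.25 higher.

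The inhibitor experiment asked which genes responded to pharmacological block of the EglN enzymes in heart. FG-4497 changed 238 of 13432 genes, 174 higher and 64 lower than with vehicle, and 38 rose and 3 fell by at least 2-fold. Adm rose most, 9.50-fold, from 7.69 ± 0.06 to 10.93 ± 0.08 (SD, n = 3; SE 0.08 on the log2 scale, limma adjusted p = 1.81e-08). Apold1, an endothelial protein induced by hypoxia, rose 5.72-fold, Depp1, a regulator of autophagy, 3.70-fold, and Ier3, an early response gene, 3.65-fold (adjusted p from 7.42e-06 to 0.000194). Bhlhe40, a transcriptional repressor linked to the clock, rose 3.43-fold, the bZIP factor Maff 3.39-fold, the protease Adamts9 3.29-fold, and Ero1a, the oxidase of the endoplasmic reticulum, and Acer2, a ceramidase, 3.17-fold each. With the mean of its probe sets, the log2 rise of Acer2 was 0.96 in place of 1.66. Pfkp, the platelet form of phosphofructokinase, rose 2.97-fold (adjusted p = 7.42e-06). Egln3 and Vegfa rose 2.12-fold and 2.09-fold (adjusted p = 7.99e-05 and 5.38e-05), while Egln2, Hif1a and Epas1 did not pass, with log2 differences of 0.14, -0.25 and -0.07.

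Falls in heart were led by Aplnr, the apelin receptor of endothelium (log2 -1.68, SE 0.12, adjusted p = 4.53e-05), the death ligand Tnfsf10 (-1.17) and Sox18, a transcription factor of endothelium (-1.11). The immunoregulatory surface protein Cd200 fell by 0.94, Car3, a carbonic anhydrase, by 0.88, and Id3, an inhibitor of bHLH factors, by 0.82 on the log2 scale, the calls of Car3 and Id3 being lost in 2 of 14 and 2 of 15 alternatives. Below these were the repressor Prdm1 (at least 0.61 lower, to values below the filter level), the protocadherin Pcdh18 (-0.77), Aqp7, a glycerol channel (-0.76), and the adaptor Dok4 (-0.76).

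HIF targets rose together in the inhibitor-treated hearts. The list's median log2 change was 0.76 (cameraPR, adjusted p = 6.35e-134), with 19 of 30 measured members higher, 0 lower, and 27 higher when adjusted over the list alone. Among them, beside Adm, Bhlhe40 and Ero1a, were Pfkfb3, up 2.82-fold, and, named after their values were seen, the glucose transporter Slc2a1 at 1.39, Ddit4, an inhibitor of mTORC1, at 1.37, and the lactate transporter Slc16a3 at 1.10. Glycolysis genes had a median of 0.17 (adjusted p = 2.13e-15; adjusted p = 1.1e-08 with an estimated correlation), with 5 of 15 higher, 7 when adjusted over the list alone: Pfkp at 1.57, Pfkl at 0.89, Pgam1 at 0.70, Ldha at 0.52 and Hk2 at 0.44. Glycogen genes had a median of 0.24 (adjusted p = 1.28e-05; adjusted p = 0.01 with an estimated correlation), with 1 of 11 higher, the glycogen-targeting phosphatase subunit Ppp1r3c at 1.21, and 5 when adjusted over the list alone. Immediate early and heat shock genes had a median of 0.28 (adjusted p = 2.72e-14; adjusted p = 1.3e-15 with an estimated correlation), with 5 of 12 higher and 7 when adjusted over the list alone. For this list the estimate was below 0 and was set to 0, so the second test was the less strict. Called were Egr1 at 1.08 (call lost in 5 of 15 alternatives), Junb at 0.64, Fosb at 0.59 (lost in 1 of 14) and Fos at 0.50 after Ier3, and none of the heat shock genes. The interferon response list fell by the preset test (median -0.15, adjusted p = 0.00417), a call lost at adjusted p = 0.27 with an estimated correlation. Of 9 members 0 were called and 3 were lower when adjusted over the list alone, Ifit2 widest at -0.43.

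Markers of endothelium moved in both directions in heart. The list was called upward (adjusted p = 0.03; adjusted p = 0.0234 with an estimated correlation) with a median of 0.011. Its estimated correlation was below 0 and was set to 0, so the second test was the less strict. Cldn5, the tight junction protein, at 1.44 and Flt1, a VEGF receptor, at 0.46 were called, the latter with its call lost in 7 of 15 alternatives. Of 12, 5 were higher and 2 lower when adjusted over the list alone, the lower being the receptors Tek and Tie1. This call was lost without vehicle replicates 1 and 2 and FG-4497 replicate 2 (adjusted p of 0.0669, 0.0908 and 0.121), with quantile normalization repeated (adjusted p = 0.14, median -0.01) and with the filter at the 60th percentile (adjusted p = 0.0601). Of cardiac stress genes 1 of 10 was higher, Mt2, a metallothionein, at 0.89 (call lost in 4 of 15 alternatives), and the list was not called (adjusted p = 0.456). Postn, a matrix protein of fibroblasts, fell by 0.42 (adjusted p = 0.0315; call lost in 8 of 15 alternatives) in a fibroblast and matrix list that was not called (adjusted p = 0.206). Alas2 rose by 0.96 (adjusted p = 0.00806; call lost in 1 of 15 alternatives), and Ciart, a repressor of the clock, by 1.00 (adjusted p = 0.00254) in a circadian clock list that was not called (adjusted p = 0.219). Cardiomyocyte (adjusted p = 0.963), macrophage and leukocyte (0.963) and smooth muscle and pericyte markers (0.963) were not called, nor were the other 11 lists (adjusted p from 0.608 to 0.995). All 238 called genes had groups that did not overlap, against 15.4% of all tested genes. The count of 238 became 147 with no filter on low values, 372 with a trended, robust prior and 445 with all 18 arrays in 1 fit. It was 144 and 137 without vehicle replicates 2 and 3 and 157 without FG-4497 replicate 1.

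**Figure D3:**
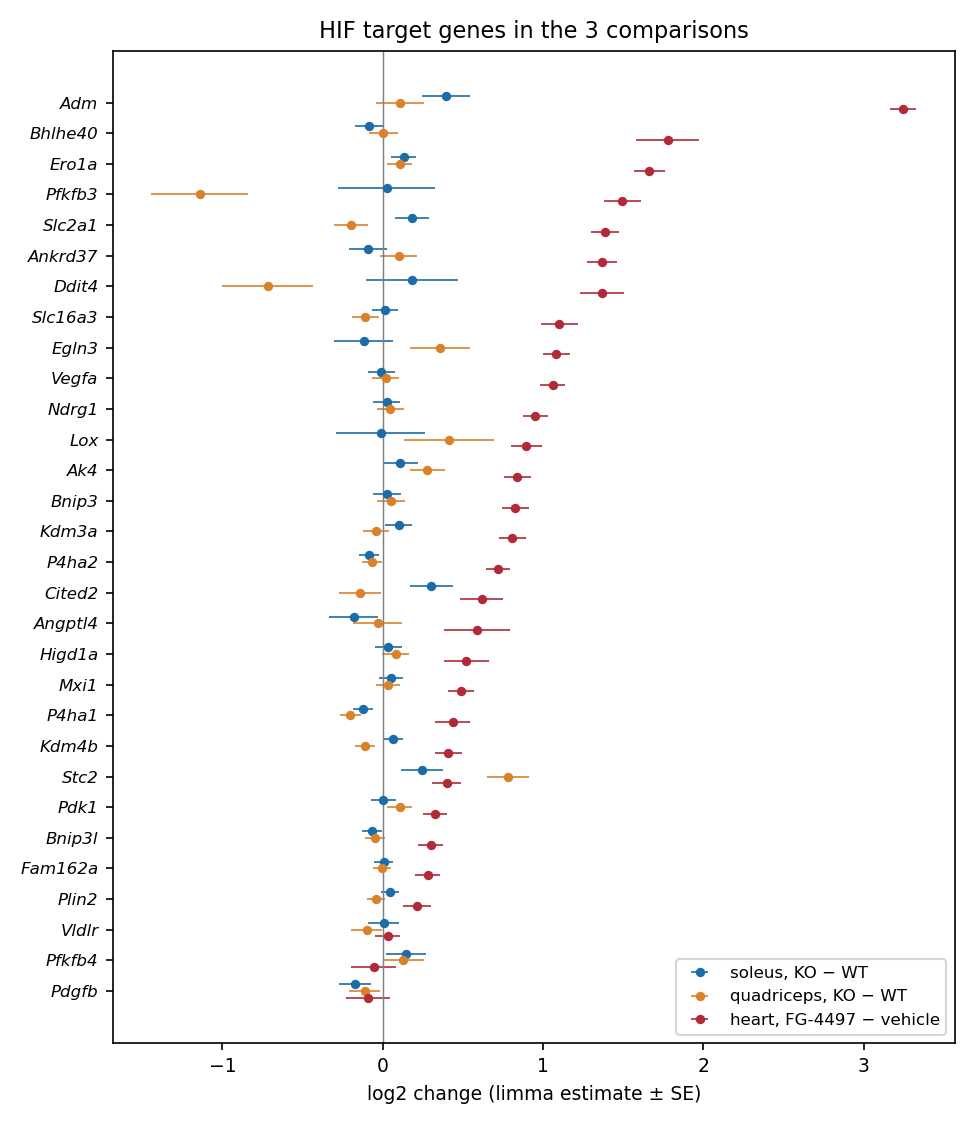
Log2 change of the 30 measured HIF target genes (limma estimate with its SE) in KO soleus, KO quadriceps and FG-4497-treated heart, ordered by the change in heart. The heart list had a median of 0.76 and reached 3.25 for Adm, while the soleus and quadriceps medians were 0.025 and 0.0007.

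Knockout and inhibitor were last compared gene by gene. Across the 12949 genes tested in both experiments, log2 changes in heart correlated with those in KO soleus at r = -0.06 and in KO quadriceps at r = -0.04. Called genes shared with heart were 2 for soleus, where independent lists would share 0.365 (Fisher's exact test, p = 0.0508), and 5 for quadriceps, where they would share 1.48 (p = 0.0162). Named here after their values were seen, the pair shared with soleus were G0s2, an inhibitor of triglyceride lipase that rose in both (0.47 and 0.83), and Mid1ip1, higher in KO soleus and lower in heart (0.53 and -0.66). The 5 shared with quadriceps were Gadd45b, a stress-induced gene that rose in both (0.68 and 0.88), Mid1ip1, Car4 and Lpar6, higher in KO quadriceps and lower in heart, and Smtnl2, lower in quadriceps and higher in heart. The heart labels give no animal numbers, and the experiments differed in tissue and in the means of blocking the enzyme.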

Additional observations from a re-analysis of the deposited data

Results flagged for a closer look

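The tests of gene position, of fibre content and of the clock described below were chosen after the results were seen. The splits of animals or arrays were planned before. They were also applied to fatty acid oxidation in quadriceps and to the clock gap, which are patterns picked from the results. Lists were picked out here where the difference of KO effects (soleus minus quadriceps) was called: oxidative phosphorylation at a median of -0.071, fatty acid oxidation at -0.23 and muscle regeneration at -0.21. The TCA cycle at -0.083 and the slow fibre list at -0.27 were called with the preset correlation alone (adjusted p = 0.166 and adjusted p = 0.957 with an estimated correlation), and the slow fibre median turned to 0.037 without the animal of soleus KO replicate 2. Signal was also present in probe sets outside the gene tables, those without 1 gene name: 20 were called in soleus, 24 in quadriceps and 31 in heart.

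Every split other than the real one mixes both real groups on each side. A real difference then raises the variance within those sides, which lowers the count of calls, and part of it stays in the list medians. The other splits are therefore no chance level for a real difference. With 10 splits of 6 animals or arrays, too few for a share under 0.05, the real split stood as follows. It alone reached its own count for soleus (1 split; 24 genes, highest other 1), quadriceps (1 split; 91, highest other 1), WT muscles (1 split; 6085, highest other 0), heart (1 split; 238, highest other 1) and genes shared by both KO muscles (1 split; 16, highest other 0, where with at most 1 gene per muscle none could be expected). For the difference of KO effects, all 10 splits reached 0, and the highest other was 0. HIF targets had a median as far from 0 in 5 splits in soleus (0.025, widest other -0.051), 10 in quadriceps (0.0007, widest other -0.054) and 1 in heart (0.76, widest other 0.277). Fatty acid oxidation in quadriceps (0.17, widest other -0.111) and the clock gap (0.748, widest other 0.655) were each reached by 1 split.

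Genes called in the KO muscles lay near each other in the genome: 24 of 94 had another called gene within 10 tested genes, against a median of 12 in random sets, which argues against random position (permutation p = 0.0109). Near Egln1 itself, 4 of 66 genes were called (Abcb10, Def8 and Trappc2l among them; 6.06% against 0.685% elsewhere, Fisher's exact p = 0.00124), which may point to a flanking segment of another strain kept with the targeted gene, although the labels give a C57BL/6 background. Without those, called genes still lay together (21 of 90, random median 11, permutation p = 0.0244), which could mean further strain segments, or neighbours that respond together. Of the 237 heart calls 77 had another called gene that near, against a random median of 71 (permutation p = 0.256), so grouping beyond random sets was not seen in heart. Heart calls lay together 1.08 times as often as random sets against 2 times for the KO calls. These ratios were not tested against each other and the lists held 237 and 94 genes, so grouping of any called list remains open. Of the 24 grouped genes 22 were tested in heart and 0 were called the same way there, so a response to lost EglN activity limited to skeletal muscle remains possible.

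The rise of fatty acid oxidation genes in KO quadriceps could come from more slow fibres in those samples. With the slow fibre level in the fit the list median stayed at 0.174, which argues against that. Among random lists matched on the ratio of soleus to quadriceps and on signal, it lay at percentile 99.62 (matched median 0.062, middle 95% of the random lists -0.0075 to 0.137). The random lists held unrelated genes, while the genes of fatty acid oxidation move together (estimated correlation 0.27), so the random spread is too narrow. Matching was also incomplete, with a median log2 ratio of 1.04 in the list against 0.92 and a signal of 11.58 against 11.10. Soleus-like tissue as a cause therefore remains open. Adipocyte markers had a median of 0.25 in KO quadriceps and were not called (adjusted p = 0.133), so a part of the rise may come from fat in the samples, which was not tested. In KO soleus their median was 0.19, also not called (cameraPR, adjusted p = 0.282), while that of fatty acid oxidation was -0.04 (adjusted p = 0.401). A shift toward oxidative fast fibres was not tested either. Myh2 had means of 12.15 in KO and 11.75 in WT quadriceps. Its arrays overlapped, at 11.92, 12.49 and 12.03 in KO and 11.96, 11.99 and 11.30 in WT.

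The clock list was called in KO soleus (adjusted p = 0.00529; 0.469 with an estimated correlation), with 0 members passing over all genes, and not in KO quadriceps (adjusted p = 0.0917), where Arntl alone passed. The gap between Arntl with Clock and their targets was 0.721 in soleus and 0.775 in quadriceps, against 0.185 in heart. It used 12 of the 14 tested genes of the list, without Cry1 and Cry2. All 12 differed with the same sign in both muscles. By the labels' numbers both muscles came from the same animals, and the labels give no harvest time for them. A different time of day at harvest and an effect of EglN1 loss on the clock could each give these values, and they cannot be told apart here.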

How the results depend on the processing

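The slow fibre covariate and the fit without a pair of arrays were chosen after the data were seen. The count of 24 in soleus was 62 with estimated array weights, 12 from the 6 soleus arrays alone and 15 without the array farthest in fibre markers in each muscle, and 7 to 43 with 1 array left out. The count of 91 in quadriceps was 42 without a filter (more genes tested), 197 with array weights, 25 from the 6 quadriceps arrays alone, 48 with the slow fibre covariate and 33 without that pair of arrays, and 27 to 75 with 1 array left out. For the difference of KO effects the count of 0 was 1 with quantile normalization repeated, 1 with the 60th percentile filter, 2 with a trended, robust prior and 2 with array weights, and 0 to 2 with 1 animal left out. WT soleus against quadriceps stayed within 1.5 times its count throughout (4585 to 5185 with 1 animal left out). Heart gave 147 without a filter, 372 with a trended, robust prior and 445 with all 18 arrays in 1 fit, and 137 to 193 with 1 array left out. The HIF target list kept its side of the threshold in each comparison, with medians of 0.0056 to 0.067 in soleus, -0.017 to 0.019 in quadriceps and 0.743 to 0.799 in heart with 1 array left out. Where fewer arrays or more genes do not account for a change, the cause was not tested.

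The direction of a list's test was compared where the main or the alternative result was called. It turned for fibroblast and matrix in soleus without soleus KO replicate 3 (0.24, lowest -0.21 without KO replicate 2). In the difference of KO effects it turned for the slow fibre list (0.037 without the animal of soleus KO replicate 2, lowest -0.71 without that of WT replicate 2, 0.031 without the pair of arrays). It also turned there for macrophage and leukocyte (0.27 without the animal of soleus KO replicate 3, lowest -0.19 without that of KO replicate 1) and adipocyte (0.44 without the animal of soleus WT replicate 2, lowest -0.28 without that of WT replicate 3, 0.35 without the pair of arrays). The cause was not tested. Medians also changed sign without such a turn, as that of the endothelial list in heart (-0.023 without vehicle replicate 2). Of the lists called, 15 of 19 alternative values kept the call in soleus, 52 of 76 in quadriceps, 80 of 90 in the difference, 108 of 117 in WT muscles and 74 of 80 in heart, beside the HIF list. Of the named genes called, 255 of 319 alternative values kept the call in soleus, 343 of 430 in quadriceps, 1199 of 1231 in WT muscles and 503 of 533 in heart, and 0 turned direction. Among those called under every alternative were Abhd1, Gdpd3 and Trappc2l in soleus, and in quadriceps these 3 with Cacng7, Mid1ip1, Mir181a-2, Polk and Tmem267. Signal near background limits what can be seen in genes below the filter.

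Replicate numbers in the titles join KO and WT arrays of different animals. Their deviations from the group means correlated at r from -0.286 to 0.0774 in the muscles, 0 of 6 pairs above 0.1, so no pairing was seen there. In heart, where the labels give no animal numbers, r lay from -0.131 to 0.175, 2 of 3 above 0.1. Whether the numbers pair the heart samples remains open. With that replicate block the counts were 5 in soleus, 12 in quadriceps and 209 in heart.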

Other observations

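The genes of this part, and the tables read for it, were chosen after the results were seen. In heart, further genes beyond those in the report rose with FG-4497: Tiparp, a repressor of the aryl hydrocarbon receptor (log2 1.55, SE 0.09, limma adjusted p = 8.64e-06), Hilpda, an inhibitor of lipid droplet lipolysis (1.52, SE 0.08), and Wt1, a transcription factor of epicardium and of vessels (1.46, SE 0.10). Ankrd37, an ankyrin repeat protein on the HIF target list, rose by 1.37, and the secreted factors Stc1, a stanniocalcin, by 0.96 and Pgf, placental growth factor, by 0.65. Among other called genes, Foxo1 (0.70) and Hey1 (0.66) were higher, while the peptide Edn1 (-0.63), the anticoagulant receptor Thbd (-0.59), Efnb2 (-0.51), Prox1 (-0.46) and Gata2 (-0.45) were lower, beside Aplnr and Sox18.

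Genes that rose in both KO muscles had these levels in heart, where the groups were FG-4497 and vehicle. Gdpd3 read 9.18, 9.26 and 9.15 with vehicle and 9.30, 9.26 and 9.35 with FG-4497, against 9.43 and 9.02 in KO soleus and quadriceps. Trappc2l read 10.63, 10.62 and 10.77 with vehicle and 10.61, 10.72 and 10.65 with FG-4497, against 10.72 and 10.49 in the KO muscles. Abhd1 read 8.99, 7.76 and 8.94 with vehicle and 9.11, 7.40 and 7.46 with FG-4497. In KO quadriceps the probe set of a further microRNA gene, Mir30e, was higher by 0.44 (limma adjusted p = 0.0335).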
